A study of Mus musculus with 10 samples.

How the data were processed

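Messenger RNA was sequenced from the cerebral cortex of 10 mice aged 12 months, 5 carrying an HIV-1 gp120 transgene (gp120tg) and 5 wild-type (WT) controls. The gp120 protein is the surface part of the viral envelope, which binds the host receptor and a chemokine co-receptor. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, mRNA was captured on poly-T beads, libraries were made with a NEBNext Ultra kit and random primers, and sequencing was done on a NovaSeq instrument. The labels call the 5 samples of each group biological replicates, and the series' design text gives 5 mice per genotype, so each library was taken as 1 mouse. The sex of the mice, the litters and the days of dissection or library preparation are not given in the sources used here.

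The deposited table holds raw read counts per gene, with 1 column per library. The values are whole numbers with a different total in each library, and the authors' table carries no normalization. STAR, Picard, SAMtools version 0.1.18, GATK and HTSeq version 0.5.4 are named in the submitters' processing notes, without their roles or order. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads from overlapping genes on opposite strands cannot be told apart. The table lists 41880 genes. Of these, 40303 have identifiers that start with MGP_BALBcJ, the form Ensembl uses for its annotation of the BALB/cJ strain, and 1577 are numbered gene models without that prefix, called unprefixed models here. They held between 1.04% and 1.17% of the counts of a library and were kept in the tests. None of the identifiers matched the mouse gene tables at hand (0 matched), which cover the C57BL/6J reference. The files do not pair the identifiers with gene symbols, so genes are given by identifier, no function or position is stated, and checks of GC content, gene length, paralogs and cell type markers were not possible. For the same reason the 46 gene lists fixed before the data were examined (594 genes of glial, immune, synaptic, stress, metabolic and dissection marker groups) could not be tested: 0 of the lists had 5 or more members that could be recognised. The transcript of the transgene was not analysed here, because the identifiers do not show whether a row holds it.

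Library totals ranged from 16451161 to 19774880 counts. For a gene at 0 counts, a floor of 3 counts per library was used as the level that a count of 0 allows, and intervals of shares of counts are 95% Wilson intervals. Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

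The comparison of gp120tg with WT was a quasi-likelihood test in edgeR version 4.0.16 (R version 4.3.3) with TMM normalization factors, edgeR's default filter on low counts by group, robust dispersion estimates, all 10 libraries and the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 16941 genes tested were called. The tested genes held at least 99.8% of the counts of every library. Fold changes are gp120tg over WT. Their standard errors were computed as the absolute log2 fold change divided by the square root of the test's F statistic. Normalized read counts are given as CPM, scaled by library size and TMM factor. Single values per library were compared by exact two-sided permutation tests over all 252 assignments of 5 libraries to a group, for which the smallest possible p is 0.007937. Principal components were computed on log2 CPM of the tested genes.

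The test was run on simulated data first. Counts were drawn for 16941 genes from the observed means, dispersions and library sizes, each gene independently. Of these, 200 genes were changed, none of them among the genes of lowest abundance, and 16710 genes passed the filter. The test recovered 26% of genes changed 1.5-fold, 64% of genes changed 2-fold, 96% of genes changed 4-fold and 98% of genes changed 8-fold, and 4.05% of its calls were genes that had not been changed. With no gene changed it made 0 calls. The simulated libraries held no structure shared between genes, so these rates do not cover such structure in the real libraries.

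Replicates of a group were compared before they were averaged. Spearman's correlation of log2 CPM was 0.972 to 0.989 within gp120tg, 0.974 to 0.990 within WT and 0.957 to 0.979 between the groups. The most similar pairs of a group differed by 12.5 (gp120tg) and 9.15 (WT) times the variance that sampling of reads gives, so no library was a repeat of another.

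The rule for genes given individually, fixed before the data were examined, used gene symbols in all parts but 1. Of that part, the genes with the lowest p, the first 2 in each direction are given. MGP_BALBcJ_G0007527 and MGP_BALBcJ_G0019190 were chosen after their values were seen.

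The alternatives fixed in advance were 3 other scalings (RLE factors, upper-quartile factors and library totals), no low-count filter and a stricter one (CPM of at least 1 in at least 5 libraries), DESeq2 version 1.42.0, limma-voom with quality weights (limma version 3.58.1), leaving out each library, the replicate number as a block, 1 surrogate variable (sva version 3.50.0), a 2-fold minimum, a test against a 1.2-fold change, and principal components of the 500 most variable genes. A covariate of named sex-chromosome transcripts could not be built without gene symbols. 6 further alternatives were chosen after seeing the data, among them a covariate for MGP_BALBcJ_G0007527 in its place.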

Results

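Gene expression in the cerebral cortex was compared between 5 mice that carry an HIV-1 gp120 transgene and 5 wild-type mice, all aged 12 months. The series' title puts the question as what the brain transcriptome of these mice shows about the disease process. Library totals were 18795000 ± 1062000 counts (SD, n = 5) in gp120tg and 17174000 ± 1141000 (SD, n = 5) in WT, a difference that did not pass an exact two-sided permutation test (p = 0.0635). Of the 41880 genes listed, 12999 had no count in any library, and 16941 passed the filter on low counts and were tested.

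The libraries of the genotypes separated along the main axis of variation. The first principal component carried 35.8% of the variance, and the 5 gp120tg libraries scored 28.7 to 42.9 against -45.7 to -24.1 for the 5 WT libraries (exact two-sided permutation test, p = 0.007937, the smallest that 252 assignments can give). The second component carried 19.2% of the variance and did not differ between genotypes by the same exact test (p = 0.643). On it, gp120tg replicate 4 (-34.5), WT replicate 4 (-37.7) and WT replicate 5 (-40.4) lay apart from the other 7 libraries, which scored -1.87 to 31.8.

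**Figure D1:**
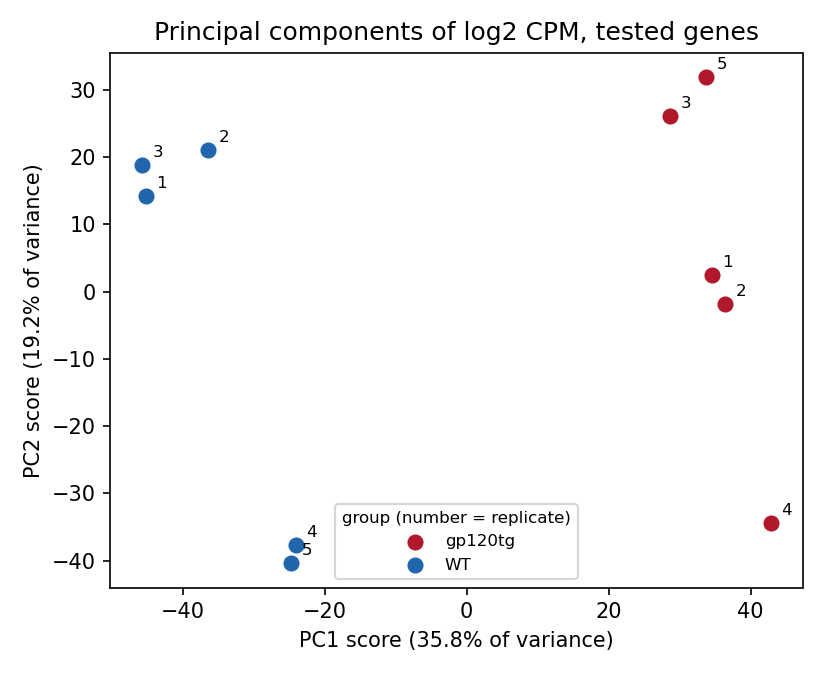
Scores of the 10 libraries on the first and second principal components of log2 CPM over the tested genes, with the share of variance on each axis; each point is 1 library and its number is the replicate. All gp120tg libraries score 28.7 or more on the first component and all WT libraries -24.1 or less, while gp120tg replicate 4 and WT replicates 4 and 5 share the low end of the second.

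Of the 16941 genes tested, 1418 (8.37%) were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Higher expression in gp120tg was more frequent than lower expression, with 1085 genes higher and 333 lower, so that 76.5% of the called genes rose. Among the called genes, those that rose also moved further, without adjustment for abundance. Their median fold change was 2.08, and the median called gene that fell was at 0.611 times its WT level. At least 2-fold changes were called for 593 higher and 119 lower genes, at least 4-fold changes for 175 higher and 34 lower genes, and at least 8-fold changes for 70 higher and 21 lower genes. Of the 712 calls of at least 2-fold, 539 lay among the 6941 tested genes of lowest abundance, so the size of the changes is not separated from abundance. The median log2 fold change over all tested genes was -0.03. The number of lower genes depended on single libraries: it was 219 without gp120tg replicate 1 and 211 without WT replicate 1, while the number of higher genes stayed between 897 and 1047 whichever library was left out. It also depended on the model: 1383 genes were higher and 524 lower with DESeq2, 1356 and 595 with 1 surrogate variable, and 804 and 198 with a term for MGP_BALBcJ_G0007527, a gene present in only some gp120tg mice.

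The groups did not overlap for most of the called genes. All 5 gp120tg libraries lay above all 5 WT libraries for 965 of the genes called higher, and below them for 268 of the genes called lower. Over all tested genes, 1128 were separated upward and 458 downward, against about 134 (0.794%) in both directions together that chance gives on average for 5 against 5. Genes vary together, so a single split can lie far from that average. A split of the libraries that crosses genotype called 2041 genes, so the excess alone is not evidence for genotype. In 185 of the genes called between the genotypes, the groups overlapped.

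The gene with the strongest evidence of a difference, MGP_BALBcJ_G0019191, rose from 165 ± 39.9 CPM in WT to 9343 ± 826 CPM in gp120tg (SD, n = 5 per group), a 56.6-fold change. Its log2 fold change was 5.82 with a standard error of 0.182 (edgeR, adjusted p = 2.85e-09). By counts it ranked 1 or 2 among all genes in every gp120tg library and 884 to 1724 in the WT libraries. It alone took up 0.951% ± 0.0878 of the counts of a gp120tg library, compared with 0.0162% ± 0.00391 of a WT library (SD, n = 5 per group; exact two-sided permutation test, p = 0.007937). The gene was chosen by its p on the same libraries, so the permutation test is not independent evidence. Whether its row holds reads of the transgene cannot be told from the identifier. The gene with the preceding identifier number, MGP_BALBcJ_G0019190, was also called higher (log2 fold change 6.11, edgeR adjusted p = 5.00e-06). It had 201 to 418 counts in the gp120tg libraries and 0 to 10 in the WT libraries. The sources used here do not state whether the numbers follow the genome, and a shared cause of the 2 changes was not tested. The gene next after MGP_BALBcJ_G0019191 in order of p, MGP_BALBcJ_G0024549, was of moderate abundance. It rose 7.26-fold, from 5.55 ± 0.385 to 40.3 ± 6.60 CPM (SD, n = 5 per group, log2 fold change 2.86, standard error 0.132, edgeR adjusted p = 1.85e-07).

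Among the genes that fell, MGP_BALBcJ_G0013230 had the lowest p. It was present at 14.4 ± 2.29 CPM in WT and nearly absent in gp120tg at 0.283 ± 0.148 CPM (SD, n = 5 per group), where the libraries held between 3 and 10 reads of it against 192 to 295 in WT. Its log2 fold change was -5.64 with a standard error of 0.271 (edgeR, adjusted p = 1.96e-07). MGP_BALBcJ_G0016221 fell from 79.6 ± 4.46 to 16.6 ± 2.89 CPM (SD, n = 5 per group; log2 fold change -2.26, standard error 0.122, edgeR adjusted p = 4.57e-07). Each of the 4 genes given for their lowest p was called in the same direction in all the alternative analyses that tested it.

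**Figure D2:**
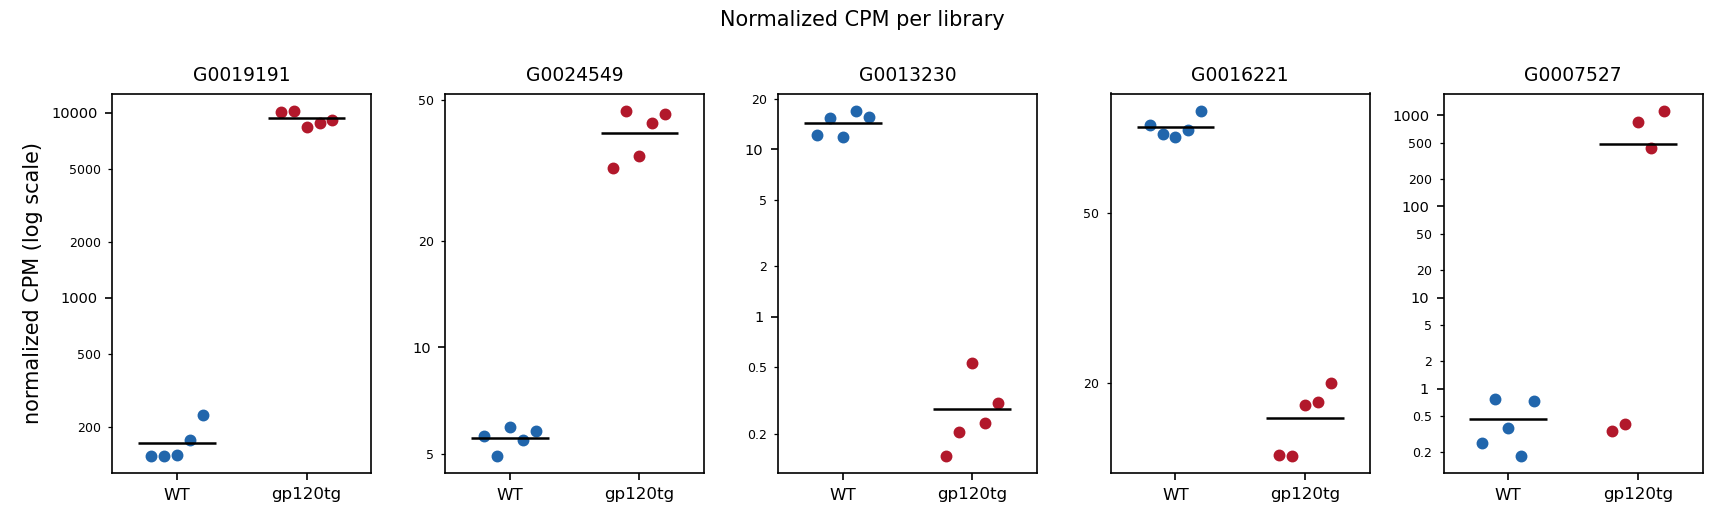
Normalized CPM on log scales, 1 point per library and a line at the mean of each group, for the 2 genes with the lowest p among those that rose (G0019191 and G0024549), the 2 among those that fell (G0013230 and G0016221) and MGP_BALBcJ_G0007527; the prefix of the identifiers is left out. The groups do not overlap for the first 4 genes, whereas G0007527 is between 0.184 and 0.773 CPM in all WT libraries and splits the gp120tg libraries into 3 high and 2 low.

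A few genes were present in one genotype only. Expression of at least 1 CPM in all 5 libraries of one group with at most 3 reads in every library of the other was found for 6 genes in gp120tg and 3 genes in WT, and all 9 were called. Against a floor of 3 counts per library, the 6 genes of gp120tg were at least 9.70-fold to at least 35.2-fold higher, and the 3 genes of WT were at least 9.53-fold to at least 33.3-fold higher than in gp120tg. Unprefixed gene models, which lack the annotation's identifier, made up 3 of the 6 and 1 of the 3.

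Calls were less frequent among abundant genes. Of the 2000 most abundant tested genes, 86 (4.3%) were called, and of the other 14941, 1332 (8.92%) (Fisher's exact test, two-sided, p = 5.08e-14, odds ratio 0.459; genes are not independent replicates). Of the 500 most abundant genes 18 were called, 11 higher and 7 lower, and only 3 of them changed at least 2-fold. Among the genes ranked 501 to 2000, 31 were higher and 37 lower. Among those ranked 5001 to 10000, 355 were higher and 88 lower, and in the remaining 6941 genes of lowest abundance 565 were higher and 145 lower. As a class, the genes called higher held 5.37% ± 0.311 of the counts in gp120tg and 2.39% ± 0.159 in WT (SD, n = 5 per group; exact two-sided permutation test, p = 0.007937). Without MGP_BALBcJ_G0019191 they still held 4.42% ± 0.228 against 2.37% ± 0.157. The genes called lower held 1.45% ± 0.0114 in gp120tg and 1.998% ± 0.0643 in WT. These classes were chosen on the same libraries, so their shares describe the size of the change and are not independent evidence of it.

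**Figure D3:**
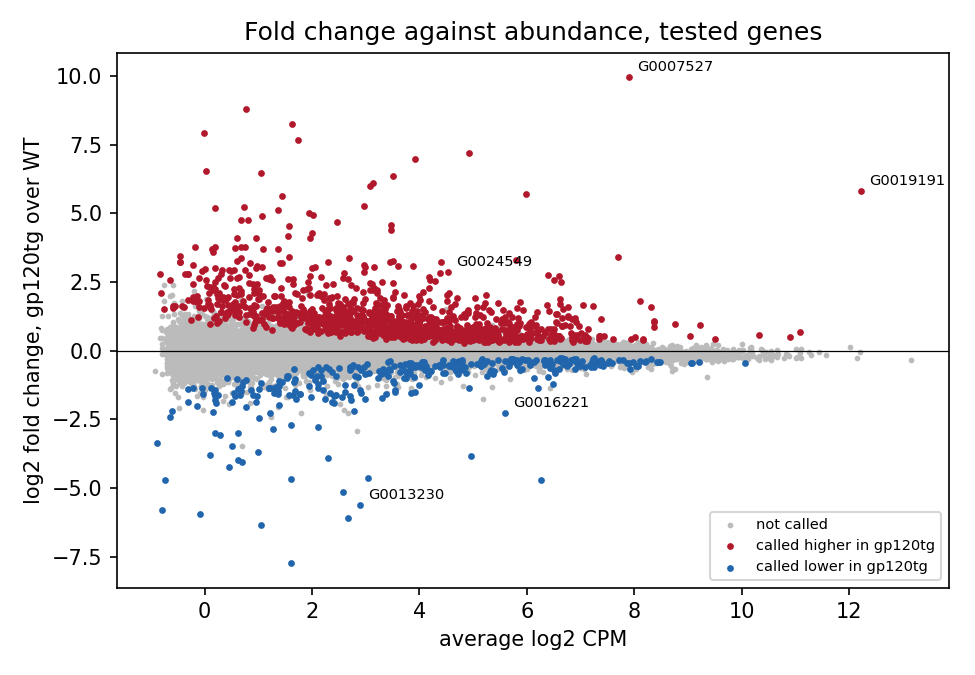
Log2 fold change of gp120tg over WT against average log2 CPM for the 16941 tested genes, with genes called at an adjusted p under 0.05 (edgeR) in red where higher and in blue where lower. The 1085 red points outnumber the 333 blue ones, and G0019191 is the most abundant of the called genes, at a log2 fold change of 5.82.

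No difference in the rate of calls was detected between unprefixed models and annotated genes. Of 982 unprefixed models tested, 88 (8.96%) were called, 43 higher and 45 lower, and of 15959 annotated genes 1330 (8.33%) were called, 1042 higher and 288 lower (rate of calls, Fisher's exact test, two-sided, p = 0.476, odds ratio 1.08, 95% interval 0.854 to 1.36; genes are not independent replicates). The direction differed: 48.9% of the called unprefixed models and 78.3% of the called annotated genes were higher (Fisher's exact test, two-sided, chosen after seeing the counts, p = 5.77e-09, odds ratio 0.264, 95% interval 0.166 to 0.420).

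MGP_BALBcJ_G0007527 differed between mice of the same genotype. It had 15911, 7466 and 22039 counts in gp120tg replicates 3, 4 and 5, 7 and 8 counts in gp120tg replicates 1 and 2, and 3 to 14 counts in the 5 WT libraries. The edgeR test called it higher in gp120tg (log2 fold change 9.96, standard error 2.13, adjusted p = 0.0137), although only 3 of the 5 gp120tg libraries showed the difference. With limma-voom and quality weights its log2 fold change was 5.06 and its adjusted p 0.696. Without the 3 libraries that hold it, the log2 fold change was -0.29 (edgeR, adjusted p = 0.873).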

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

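The tests of scaling, of library size, of the most abundant gene and of whether the calls rest on 3 libraries were written down before their results were seen; the tests of a sex difference and of that gene's share of the counts against the fold changes were chosen afterwards.

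By Dixon's test for a value far from the others of its group, 2 results stood out among 22 groups of values tested; chance flags about 1 in 20. WT replicate 5 had 19176929 counts, above the 16451161 to 17042812 of the other WT libraries. In WT replicate 1 the genes called higher in gp120tg held 2.104% of the counts (95% Wilson interval 2.10% to 2.11%), below the 2.44% to 2.48% of the other WT libraries.

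The number of called genes was compared with that of other splits of the 10 libraries into 5 and 5. Of 100 splits, the real one included, 2 called as many genes as the real split. That share is under the 0.05 set beforehand, which argues against a random assignment of libraries. The count reacts to any strong axis of the samples, so it cannot tell genotype from an unlabelled difference aligned with it. The other split with as many calls had 2041 genes, more than the 1418 between the genotypes. It set gp120tg replicates 1, 2 and 4 with WT replicates 4 and 5 against the other libraries, so it follows the second principal component and points to a structure of the samples that crosses genotype; the labels give no batch for it. With a term for that split 1773 genes were called between the genotypes, of which 1392 were among the 1418, so this structure adds spread. Both genotypes lie on each side of the split, so its term could hardly remove genotype calls. The result does not address a structure aligned with genotype. A difference in library size is argued against as well: with every library thinned to the smallest total, 1370 genes were called.

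The excess of higher over lower calls was weighed against scaling, library size, a difference in sex and the counts taken by a single gene, the first 3 of which needed the share of higher genes among the calls to fall to 60% or less. The share was at least 76.11% under the other scalings and 77.08% after thinning all libraries to the same total. The share after thinning argues against library size as the source. The other scalings lay close to the main one, with a median log2 fold change over all tested genes of -0.028 to 0.0279, against -0.0262. The lowest log2 fold change of a gene called higher was 0.2873, so they could hardly bring the share to 60%. They show only that the excess does not depend on the choice among them, and an error common to all is not addressed. Scaling by 1 factor per library also cannot address a shift that depends on abundance. The median log2 fold change was -0.141 in the 500 most abundant genes and 0.0169 in the 6941 least abundant. With the level of MGP_BALBcJ_G0007527 as a covariate or without the 3 libraries that hold it the share was at least 79.88%, which argues against a sex difference between those 3 mice and the other 7 as the source. Leaving out MGP_BALBcJ_G0019191 gave 76.5% with the other calls as before, so that this step tests nothing, although a share above 65% had been set down as evidence against that gene as the source. Its share of the counts does argue against it: the share lowers other genes in gp120tg, by at most 0.01521 log2 units, and the other 1084 genes called higher had a median log2 fold change of 1.057 and a lowest of 0.2873. The genotype and a different mix of cells in the dissected tissue stay open, and the latter could not be tested without gene names. Days of dissection or library preparation that follow genotype, and a genetic background that differs between the lines, also stay open. The labels do not allow a test of them.

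MGP_BALBcJ_G0007527 was abundant in gp120tg replicates 3, 4 and 5 and nearly absent from the other 7 libraries. If the calls between genotypes rested on those 3 mice, the log2 fold changes would shrink once its level is a covariate. Over the 1417 other called genes, the median ratio of the log2 fold change with the covariate to that without it was 1.065. All 1417 kept their sign, and 912 remained called. The genes were called on the same libraries, and in most of them every gp120tg library lay beyond every WT library. Kept signs were therefore largely fixed by that choice and are not independent evidence, although the ratio could have fallen. A candidate explanation for MGP_BALBcJ_G0007527 itself is a difference in sex between the mice, with 3 gp120tg mice of one sex and the other 7 of the other. Such a difference predicts genes with the opposite pattern: 1 gene had it, with at most 2 counts in these 3 libraries and 15 to 86 in the others, and 3 of the 120 possible sets of 3 libraries had as many. That goes with the explanation but rests on 1 gene, and a segregating variant of the 2 genes remains open. The pattern of MGP_BALBcJ_G0007527, high in 3 libraries alone, was shown by 1 gene here, and 5 of the 120 sets had as many. No result could have argued against a sex difference, since the identifiers do not show whether genes of a second sex chromosome were counted.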

How the results depend on the processing

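The covariate for MGP_BALBcJ_G0007527, the term for the split with the most calls, thinning, and the analyses without 3 libraries or without the most abundant risen gene were chosen after seeing the data. The gene list tests and their alternatives, and the covariate of named sex-chromosome transcripts, were not run, because the identifiers carry no symbols. The total of 1418 called genes stayed within 1.5 times under all alternatives but the stricter criteria: it was 712 (593 higher, 119 lower) with a minimum of 2-fold and 929 (150 lower) against a 1.2-fold change. It was 1907 with DESeq2, 1951 with 1 surrogate variable, 1002 with the covariate for MGP_BALBcJ_G0007527, 989 without the 3 libraries that hold this gene, and 1491 without the 3 libraries apart on the second component. The number of lower genes, 333, moved most: it was 524 with DESeq2, 595 with the surrogate variable, 198 with the covariate and 199 without the 3 libraries that hold the gene. Leaving out 1 library at a time gave 1124 to 1335 called genes, 897 to 1047 higher and 211 to 305 lower, of which 1082 to 1201 were among the 1418. The share of higher genes among the calls, 76.5%, was 84.2% with library totals as the only scaling, 72.5% with DESeq2, 71.9% with the term for the split, 69.5% with the surrogate variable and 68.8% without the 3 libraries apart on the second component. The log2 fold change of MGP_BALBcJ_G0007527 turned to -0.050 with its own covariate, as that covariate must do, and to -0.29 without the 3 libraries that hold it. Its call was also lost, at a log2 fold change of 9.77 to 10.22, without a low-count filter (edgeR, adjusted p = 0.0624) and without WT replicate 3, 4 or 5 (edgeR, adjusted p = 0.0698, 0.0718 and 0.0633). The call was lost too at a log2 fold change of 10.03 without the 3 libraries apart on the second component (edgeR, adjusted p = 0.216) and at 5.06 with limma-voom (adjusted p = 0.696). The first principal component separated the genotypes in all alternatives run (exact permutation p = 0.007937 for the 500 most variable genes and without single libraries). The groups share replicate numbers, but no pairing of the mice by number was detected. Deviations of same-numbered libraries correlated at -0.10, -0.02, 0.13, 0.33 and -0.17, and none of the 5 gp120tg libraries correlated best with its own number. So few libraries cannot exclude litters or days shared by number. With the replicate number as a block 1162 genes were called, 892 higher and 270 lower. In simulated data with this number and depth of libraries, and genes drawn independently, 26% of genes changed 1.5-fold were found. Structure shared between genes, such as the second component, was not simulated. Thinning all libraries to the smallest total gave 1370 calls.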

Other observations

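The test of neighbouring identifiers was written down before its result was seen; the tests of a single block of identifiers and of switching genes were chosen afterwards.

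Annotated genes that were called tended to have close identifier numbers, though not beyond the range of random draws. Of the 1330 called annotated genes, 70.3% had another called gene within 10 numbers, above the 95th percentile of 69.55% but below the highest value of 72.48% in 10000 random draws of as many tested genes (permutation p = 0.015). The block of identifiers from 23500 to 23599 held 18 called genes among 65 tested, 16 higher and 2 lower, against 8.25% called outside it; the highest block of a random draw held a median of 14 and at most 22 (permutation p = 0.012). If the numbers follow the genome, which is not stated in the sources used here, such a block may mark a region that differs between the mouse lines, around the transgene or from another strain; families of related genes that change together would give the same pattern, and the values of 70.3% and 18 do not decide between them.

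Some genes were on in some mice and off in others of the same genotype (at most 3 counts in one library and at least 5 CPM in another). There were 25 such genes in gp120tg, 4 in WT and 0 in both. A more mixed genetic background in the gp120tg mice may give such a difference, but 27 of the 126 splits of the libraries gave one as large as the observed 21 genes, so these data do not separate it from chance.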
